A study of Mus musculus with 3 samples.

How the data were processed

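The deposited files hold, for each of 3 mouse sections, a matrix of raw UMI counts per gene and spot, made by Space Ranger 1.2.0 per the file headers. STAR and the mm10 genome are named in the submitters' processing notes, while the STAR version, the annotation release and the rule that selected spots are not given in the sources used here. Sections were 10 µm thick, and spots are 55 µm across with 100 µm between centres. The stage of each section was taken from its title. Each matrix listed the same 32285 genes, of which 32158 IDs were in the reference gene table, 31436 of them under the same symbol. Genes are named by the symbols of the files. The 78 entries whose symbol is used more than once were tested and counted, but left out of the named genes and the lists. T stands for the gene also called Tbxt. Spot positions and tissue images were not used here. Computing used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

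Spots with at least 1000 UMIs were used, which left out 2 spots at E11.5, 0 at E12.5 and 5 at E13.5. UMIs per spot ranged from 350 to 80874 at E11.5, from 1032 to 67290 at E12.5 and from 627 to 59126 at E13.5. Each spot was scored within its section by the mean of log2(UMIs per 10000 + 1) over the genes of each of 6 class lists (notochord, chondrogenic, sclerotomal, tendon, myogenic and neural). The top 3% of spots formed the notochord class and the top 10% each other class. The notochord class had priority, other spots in several classes were left out, and the rest formed a 7th class. Genes that choose the spots are no finding and were left out of the named genes and lists. Spots can hold several cells, and no doublet caller applies.

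For the comparisons between classes, UMIs were summed per section and class into 21 sums, and edgeR's quasi-likelihood test (filterByExpr, TMM, glmQLFit, glmQLFTest) was fitted to them, with Benjamini-Hochberg adjustment and an adjusted p under 0.05. The sections were the block of the model, because the classes of a section come from the same tissue. Without a replicate block the fit called 0 genes higher and 0 lower in notochord spots, 0 lower in sclerotomal spots, and 0 higher and 0 lower in tendon spots. All classes shared 1 estimate of the spread per gene, so the p-values set a difference against the scatter of all 21 sums and not only of the classes compared. That scatter is over 3 sections of 3 stages, and not over embryos of 1 stage. Section log2 ratios used a pseudocount of 0.5 UMI, and a gene with 0 UMIs in both classes of a section has no direction there. Gene lists were tested with camera of limma with a preset correlation of 0.01 and again with an estimated one, over 14 lists of axial skeleton and signalling genes and 14 of other tissues, each without the genes that choose the spots and with at least 3 genes tested. Of 84 list tests, 32 passed with the preset correlation (17 higher, 15 lower) and 3 with the estimated one, namely the notochord sheath and nucleus pulposus list in notochord spots and the cartilage matrix list in sclerotomal and in tendon spots. In 7 of the 84 the median, the mean and the test differed in sign, the lowest adjusted p among them being 0.768.

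For the stages, UMIs were summed per section over a class and over all spots and scaled to a total of 1000000 (CPM). The ratio of E13.5 to E11.5 is given with an exact conditional binomial 95% interval and single values with exact Poisson intervals. A gene counted when it had at least 50 UMIs over both sections and a ratio of at least 2. A fold against a section with 0 UMIs was taken against 3 UMIs per section and is written as at least that fold, while the exact interval of such a fold reaches lower. List medians took genes with at least 20 UMIs, a pseudocount of 0.5 UMI and 10000 random lists of the same size matched on mean expression. Medians with genes at 0 are also given with those genes at their bound. In the classes the sums held 922011 and 443411 UMIs (chondrogenic, E11.5 and E13.5), 965246 and 1221634 (sclerotomal) and 1067398 and 271465 (notochord).

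Regions were found per section by Leiden clustering (resolution 1.0) on 2000 variable genes, 30 principal components and 15 neighbours, and are described by the genes with the highest ratio to the other spots among those with at least 100 CPM. Named genes followed a rule. Between classes it took, in each direction, up to 12 genes with the largest fold among those past the test in the same direction in 3 of 3 sections and with at least 100 UMIs. Between stages it took up to 10 genes with the largest ratio, at least 100 UMIs and an E12.5 value between the other 2. Globin, mitochondrial, ribosomal protein, sex-linked and unnamed genes were left out, and members of the lists were added. These choices, the lists and most alternatives were fixed before the data were examined.

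The steps were tested on simulated data. Between classes 200 genes were changed, in equal numbers 4-fold and 2-fold. Of those changed 4-fold, 67%, 77% and 83% were recovered in the notochord, sclerotomal and tendon comparisons. Of those changed 2-fold, 21%, 27% and 32% were recovered, with 3, 5 and 2 unchanged genes called. Between stages 90.5%, 83.5%, 93.0% and 99.5% of genes changed 4-fold were recovered in chondrogenic, sclerotomal, notochord and all spots, while 45, 22, 90 and 7 unchanged genes passed 2-fold by counting error.

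Alternatives tried were DESeq2's Wald test, its size factors in edgeR, no filter on low counts, shares of spots at 1.5% and 5% or at 6% and 20%, scores from z-scores, spots of several classes put in the class of highest rank, spots of any depth, totals without globin, mitochondrial and ribosomal protein genes, a model of only the 2 classes compared, each section left out in turn, TMM factors between stages, at least 10 UMIs per gene with a pseudocount of 0.5 UMI, at least 200 UMIs per gene, at least 100 UMIs or a pseudocount of 5 UMI for lists, and Leiden resolutions of 0.5 and 1.5. The notochord class chosen by T alone, spots with over 1000 CPM of heart genes (Myl7, Myh6, Tnni3) left out, and spots with at least 5000 UMIs were added after seeing the data.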

Results

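To describe gene expression across the forming vertebral column and its intervertebral discs, 3 frozen sections of mouse embryonic axial skeleton were profiled with Visium, a slide on which RNA from a tissue section is captured on an array of barcoded spots. One section was taken at each of embryonic days E11.5, E12.5 and E13.5, so that each stage holds 1 section and no replicate. Each spot is 55 µm across and can hold several cells. The E11.5 section covered 1563 spots with 44359910 UMIs (unique molecular identifiers, each standing for 1 captured RNA molecule), the E12.5 section 1014 spots with 25490744 UMIs and the E13.5 section 1365 spots with 28754555 UMIs. The median spot held 27009 UMIs from 6159 genes at E11.5, 24385.5 UMIs from 6184.5 genes at E12.5 and 20931 UMIs from 5840 genes at E13.5. Globin transcripts, from blood, made up 5.44% of the UMIs at E11.5, 1.40% at E12.5 and 0.780% at E13.5.

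To set the tissues of the axial skeleton side by side, spots were assigned to classes by the mean level of short lists of well-known genes. The notochord, the midline rod that becomes the nucleus pulposus of the disc, was scored by T, Shh and Chrd (Noto held 0 UMIs in each section). Cartilage was scored by genes such as Col2a1, Acan and Sox9, sclerotome, the somite derivative that forms vertebrae and the outer disc, by genes such as Pax1, Pax9 and Nkx3-2, and tendon by Scx, Tnmd, Fmod, Kera and Mkx. Below, these classes are called notochord, chondrogenic, sclerotomal and tendon spots. A class is a range of a score and not a cell type. At E13.5, 8 spots lay within 0.1 SD of the boundary of the notochord class and 39 spots within 0.1 SD of that of the chondrogenic class. Outside the notochord class, between 68 and 146 spots per section met more than 1 class and were left out. At E11.5, 95 spots scored as both chondrogenic and sclerotomal, and those of them in the notochord class were kept there.

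The notochord class held 47, 30 and 41 spots at E11.5, E12.5 and E13.5, and the chondrogenic class 36, 39 and 70. The sclerotomal class held 40, 39 and 66 spots, and the tendon class 80, 50 and 80. Cartilage and notochord spots were shallow at E13.5, with a median of 4743.5 and 5119 UMIs, against 18171.5 in sclerotomal spots and 20979 in tendon spots of the same section. At E11.5 the chondrogenic spots also held heart transcripts: Myh6, Myl7, Myl2 and 4 further heart genes summed to 1747 CPM (UMIs scaled to a total of 1000000 per section and class) there, against 8.57 at E12.5 and 331.5 at E13.5. Notochord spots held 1241 CPM of neural crest and Schwann cell genes at E11.5 and 629.97 at E12.5, most of them from Fabp7.

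**Figure D1:**
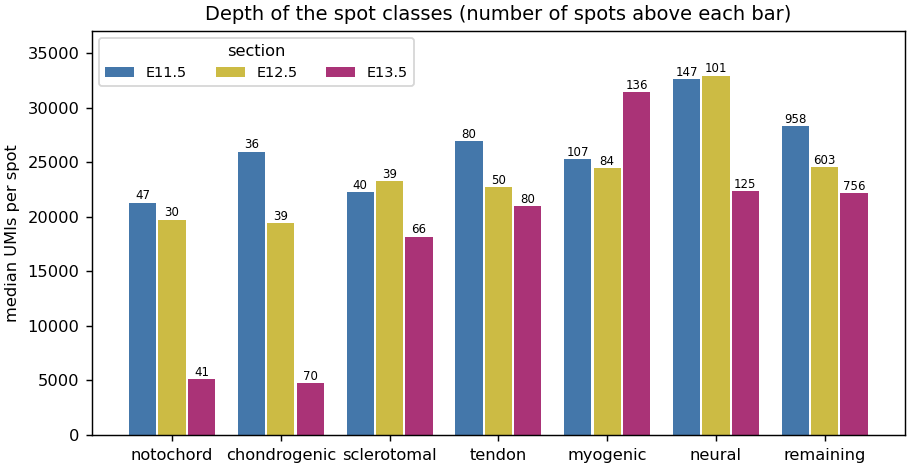
Median UMIs per spot (vertical axis) in each spot class, with 1 bar per section (E11.5, E12.5, E13.5) and the number of spots above it. At E13.5 the chondrogenic and notochord bars stand at 4743.5 and 5119 UMIs, below the sclerotomal bar at 18171.5.

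To see which regions the spots formed without those lists, the spots of each section were clustered, which gave 21 regions at E11.5, 17 at E12.5 and 16 at E13.5. At E11.5, a region of 89 spots was led by the cartilage genes Col9a3, Wwp2, Matn4 and Col2a1 together with Pax1, a sclerotome transcription factor, and 14 notochord, 3 chondrogenic and 2 sclerotomal spots lay in it. The other E11.5 chondrogenic spots lay elsewhere, 9 of the 36 in a region led by Penk, Tbx1 and Mecom, 6 in one led by the heart genes Myl2, Nppa and Myh7 and 5 in one led by Gsc and Pitx1. Of the 47 notochord spots at E11.5, 11 lay in a region led by Fgfbp3, Prdm8 and AW047730 that also held Ntn1 and Fam183b, and 4 in an epithelial one led by Aldh1a3, Sfn and Epcam. At E12.5 cartilage genes led more than 1 region. Hapln1, Gdf10 and Col9a1 led 47 spots, T, Epyc, Susd5, Acan and Shh led 33 spots that held 17 notochord and 10 chondrogenic spots, and Pax1, Foxf1, Foxf2 and Pax9 led 49 spots. At E13.5 a region of 25 spots, 24 of them in the notochord class, was led by T, Car3, Spp1, Krt8, Susd5 and Krt19. A region of 130 spots with 52 of the 70 chondrogenic and 12 of the 41 notochord spots was led by Comp, Matn1, Matn4 and Col11a2. Another of 87 spots was led by Fmod, Col2a1, Ucma and Chad, and one of 86 spots, with 30 of the tendon spots, by C1qtnf3, Tnmd and Thbs4. A region of 12 spots at E13.5 was led by Ibsp, Col10a1, Panx3 and Ifitm5, genes of hypertrophic cartilage and bone, and its liver genes were higher too (mean log2 ratio to the other spots 3.01).

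To find what sets notochord apart from cartilage, notochord and chondrogenic spots were compared over the 3 sections. Secreted guidance cues, keratins and Car3 were among the genes higher in notochord spots. Ntn1, a secreted axon guidance cue, stood at 171, 380 and 55.3 CPM at E11.5, E12.5 and E13.5 against 14.1, 14.7 and 22.6 in chondrogenic spots (log2 fold change 3.62, adjusted p = 0.0251, section log2 ratios 3.15 ± 1.72 SD). Slit1 and Slit2, ligands of Robo receptors on growing axons, were higher by 5.22 (adjusted p = 0.00304) and 3.08 (adjusted p = 0.0379) on the log2 scale. Car3, a carbonic anhydrase, was higher by 4.19 (adjusted p = 0.00409) and reached 6218 CPM in notochord spots at E13.5 against 156 in chondrogenic spots. The simple epithelial keratins Krt8 and Krt18 were higher by 3.89 (adjusted p = 0.0355) and 3.04 (adjusted p = 0.0443), and Foxa2, a forkhead factor of the notochord and floor plate, by 5.98 (adjusted p = 0.0379).

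In that comparison, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 24 genes higher and 2 lower of 12580, and each of the 26 had the same direction in 3 of 3 sections. The other named genes were Fam183b (log2 fold change 6.63), Cmtm8 (4.56), Ccdc3 (4.12), Cadm3 (4.10), a neural adhesion molecule, Fabp7 (3.89), a fatty acid binding protein of radial glia and Schwann cell precursors, and Metrnl (2.87). Fabp7 stood at 1216, 591 and 346 CPM in the notochord spots of the 3 sections. At E13.5 some directions rest on very few UMIs, where 1 UMI is 3.68 CPM in notochord and 2.26 CPM in chondrogenic spots. There Cmtm8 and Cadm3 stood at 3.68 against 2.26 CPM, Ccdc3 at 7.37 against 4.51 and Fam183b at 3.68 against 0. For these genes a repeat in the E13.5 section is not shown. Lower in notochord spots were Cytl1, a secreted protein of cartilage (log2 fold change -2.82, adjusted p = 0.0379), and Clmp, a cell adhesion protein (-1.03, adjusted p = 0.0355, section log2 ratios -1.04 ± 0.14 SD). The counts depended on single sections: without E12.5 0 genes were higher and 0 lower, without E11.5 the counts were 3 and 0, and without E13.5 they were 77 and 13. With the notochord class chosen by T alone, 1 gene was higher and 0 were lower. Within the class the guidance genes were higher in spots with Shh and no T: at E12.5 Ntn1 stood at 1191 CPM there against 92.1 in spots with T, and Slit1 at 289 against 20.9. Car3 lay in spots with T at both E11.5 (303 against 19.8 CPM) and E12.5 (414 against 11.8). Krt8 did so at E12.5 (289 against 17.7) but was level at E11.5 (112.5 against 116).

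Among the gene lists, the notochord sheath and nucleus pulposus list was higher in notochord spots as a group. Of its 11 measured members 5 were higher (Car3, Ntn1, Krt8, Foxa2 and Krt18), and 10 were higher when adjusted over the list alone, which added Lgals3, Krt19, Foxa1, Cd24a and Epcam. The median log2 fold change was 3.04, and camera's adjusted p was 5.4e-24 with the preset correlation and 0.000221 with an estimated correlation. Within the class, Foxa2 was higher in spots with Shh and no T at E11.5 (71.8 against 15.8 CPM with T) and E12.5 (153 against 2.09). Ntn1 was higher there too. Car3 lay in spots with T in both sections, and Krt8 and Krt18 did so at E12.5 but not at E11.5. The list can therefore be higher in part through spots without T. Genes of other epithelia were higher beside it, epidermis with a median of 1.75 (adjusted p = 0.0172 but 0.407 with an estimated correlation) and lung and gut epithelium with 1.61 (adjusted p = 0.0375 but 0.407 with an estimated correlation). In camera neural crest and Schwann cell genes were higher too (median 0.065, adjusted p = 0.0278). Limb (-1.61, adjusted p = 0.0375) and erythroid genes (-0.76, adjusted p = 0.0278) were lower, each of these 3 lists at 0.407 with an estimated correlation. Adult globins were also lower (-0.76, adjusted p = 0.0490 but 0.554 with an estimated correlation). The cartilage matrix list did not separate the classes (0 of 18 members past the test, median -0.33, adjusted p = 0.359), although without the E11.5 section it was lower in notochord spots (adjusted p = 0.000283). Of the 47, 30 and 41 notochord spots in the 3 sections, 16, 22 and 8 also met the chondrogenic class and were kept as notochord spots. The choice of spots can therefore set part of this likeness. Mesenchymal transcription factors were lower as a group (median -0.57, adjusted p = 0.000615 but 0.407 with an estimated correlation), with 0 of 14 members past the test and Meox2 lower when adjusted over the list alone. Notch genes were higher as a group (adjusted p = 0.0278 but 0.554 with an estimated correlation), and Hey1, Hes5 and Nrarp were higher when adjusted over the list alone, each in 2 of 3 sections.

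**Figure D2:**
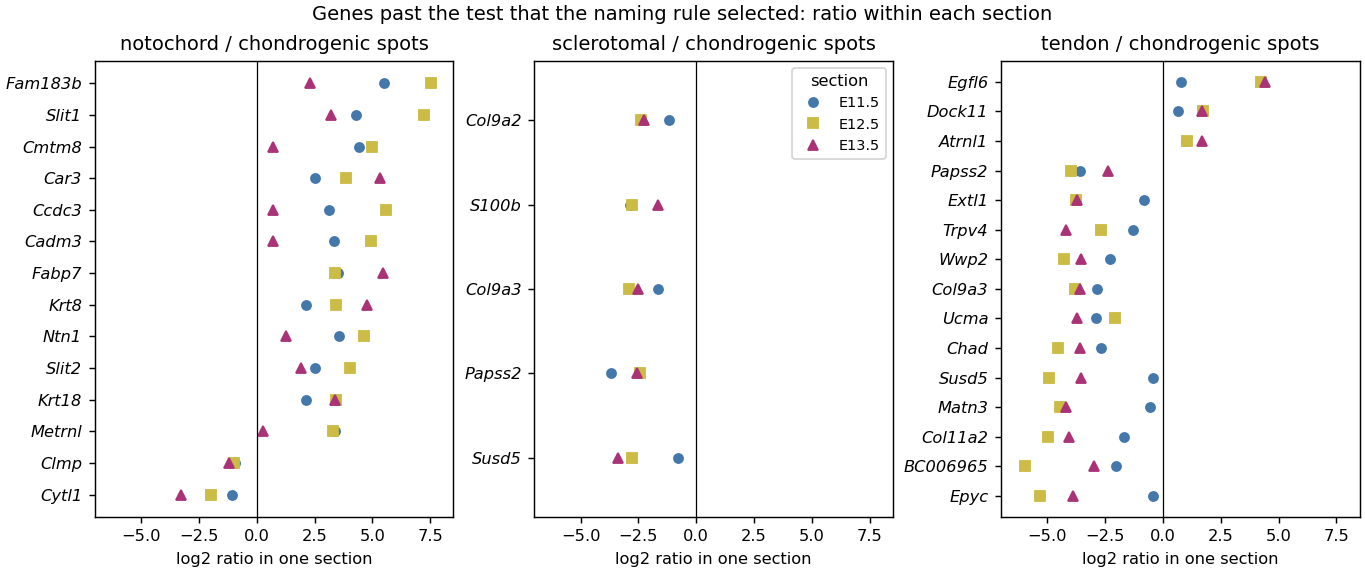
Log2 ratio of each named gene between 2 spot classes (horizontal axis), with 1 point per section, for notochord, sclerotomal and tendon spots against chondrogenic spots in the 3 panels. Col9a3 lies at -2.35 ± 0.65 (mean ± SD of the sections) in sclerotomal spots and at -3.42 ± 0.48 in tendon spots.

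To find what separates sclerotome from cartilage, sclerotomal and chondrogenic spots were compared in the same way. Cartilage matrix genes were lower in sclerotomal spots. Col9a3 and Col9a2, chains of collagen IX, were lower by a log2 fold change of -2.53 (adjusted p = 0.0153) and -2.10 (adjusted p = 0.0392). Col9a3 stood at 46.6, 273 and 1164 CPM in sclerotomal spots at E11.5, E12.5 and E13.5 and at 146, 2064 and 6590 in chondrogenic spots. Papss2, which makes the sulfate donor for proteoglycans, was lower by -2.80, Susd5 by -3.05 and S100b, a calcium-binding protein of chondrocytes and glia, by -2.24 (adjusted p = 0.0392 each). Each of these 5 genes was lower in 3 of 3 sections. For 2 of them the E11.5 direction rests on few UMIs, with Susd5 at 1.04 against 2.17 CPM and S100b at 0 against 3.25. Spots that scored as both sclerotomal and chondrogenic, 95, 48 and 40 in the 3 sections, were in neither class, some of them being kept as notochord spots. The chondrogenic class was also chosen by cartilage genes, so the choice of spots sets part of this direction. With such spots put in the class of highest rank 0 genes were lower, and the log2 fold change of Col9a3 was -1.77.

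By edgeR's quasi-likelihood test 0 genes were higher in sclerotomal spots and 5 were lower. At an unadjusted p under 0.05 there were 993 genes in both directions together, DESeq2 called 2 higher and 19 lower, and a model of only the 2 classes called 52 higher and 78 lower. Of the 18 measured cartilage matrix genes 3 were lower, and 18 were lower when adjusted over the list alone (median log2 fold change -2.28). Camera's adjusted p for that list was 9.8e-34 and 0.0194 with an estimated correlation. Other cell types moved with the class: endothelial genes were higher as a group in sclerotomal spots (median 1.39, adjusted p = 7.4e-07 but 0.268 with an estimated correlation), and 4 of 5, Kdr, Pecam1, Emcn and Cldn5, were higher when adjusted over the list alone. Neural crest and Schwann cell genes were higher too (median 1.44, adjusted p = 5.8e-05 but 0.268 with an estimated correlation), and glycolysis and hypoxia genes lower (median -0.65, adjusted p = 1.0e-07 but 0.2999 with an estimated correlation), with P4ha1, P4ha2, Pdk1 and Hk2 lower when adjusted over the list alone. Macrophage genes (median 1.07, adjusted p = 0.000948) and Notch genes (0.73, adjusted p = 5.8e-05) were higher, both 0.407 with an estimated correlation. Heart genes (median -1.95, adjusted p = 0.0278 but 0.554 with an estimated correlation) and limb genes (-1.80, adjusted p = 0.00368 but 0.210 with an estimated correlation) were lower. Without the E12.5 section 0 genes were lower, and with spots of at least 5000 UMIs 1 gene was lower.

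To compare tendon with cartilage, tendon and chondrogenic spots were tested over the 3 sections. The cartilage programme was lower in tendon spots as a block. Col11a2, a chain of collagen XI, stood at 3.98, 18.4 and 334 CPM in tendon spots at E11.5, E12.5 and E13.5 and at 13.02, 597 and 5525 in chondrogenic spots (log2 fold change -3.97, adjusted p = 0.00193, section log2 ratios -3.58 ± 1.70 SD). Col9a3 (-3.46, adjusted p = 0.000307), Wwp2, a ubiquitin ligase gene expressed with Sox9 in cartilage (-3.46, adjusted p = 0.000715), and chondroadherin, Chad (-3.66, adjusted p = 0.00193), were lower in 3 of 3 sections. The small proteoglycan gene Epyc (-4.07), the matrilin Matn3 (-3.87), Ucma (-3.51), the calcium channel Trpv4 (-3.45), Susd5 (-3.69), Papss2 (-3.25), Extl1 (-3.35) and BC006965 (-4.00) were lower as well. Higher in tendon spots was Egfl6, a secreted matrix protein (log2 fold change 3.71, adjusted p = 0.0027), at 213 CPM at E13.5 against 9.02 in chondrogenic spots. Atrnl1 (1.23, adjusted p = 0.00816) and Dock11, an activator of Cdc42 (1.43, adjusted p = 0.0311), were higher with smaller ratios. Here too spots of both classes were left out and cartilage genes chose the chondrogenic spots. With such spots put in the class of highest rank 13 genes were higher and 47 lower, Col9a3 by -2.87 and Col11a2 by -3.28.

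For tendon against chondrogenic spots edgeR's quasi-likelihood test called 9 genes higher and 38 lower, and 39 of the 47 had the same direction in 3 of 3 sections. Some of these directions rest on few UMIs at E11.5, where Matn3 stood at 0.884 CPM in tendon and 1.08 in chondrogenic spots. Of 18 measured cartilage matrix genes 13 were lower and 18 when adjusted over the list alone, with a median of -3.46 and an adjusted p of 1.3e-51 in camera, or 0.00496 with an estimated correlation. Among the 13, Comp was lower in 2 of 3 sections. The fibrous connective tissue list, collagens I, III and VI among it, was higher as a group (median 0.43, adjusted p = 0.00901 but 0.669 with an estimated correlation) with 0 of 20 members past edgeR's test and 0 when adjusted over the list alone. Other cell types were higher in tendon spots too: epidermis (median 1.95, adjusted p = 0.00353) and endothelium (1.04, adjusted p = 0.00349), both 0.407 with an estimated correlation. Macrophage genes (0.96, adjusted p = 0.0262 but 0.554 with an estimated correlation) and embryonic globins (0.91, adjusted p = 0.0278 but 0.407 with an estimated correlation) were higher as well, as were Notch genes (0.72, adjusted p = 0.00353 but 0.407 with an estimated correlation). In the hedgehog response list, 0 of 11 members passed over all genes. Adjusted over the list alone, the receptor Ptch1, its target Gli1 and Foxf2 were lower and the co-receptors Gas1 and Cdon higher (camera adjusted p = 0.235). Without the E12.5 section the counts were 0 higher and 3 lower, without E11.5 they were 16 and 52, and without E13.5 they were 1 and 11.

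To follow cartilage over time, chondrogenic spots of the E13.5 section were compared with those of the E11.5 section. With 1 section per stage, embryo and section plane differ together with the stage and no test was possible. Ratios are given with 95% counting intervals, which cover counting error only. Cartilage matrix transcripts were far higher at E13.5. Col11a2 stood at 13.02, 597 and 5525 CPM at E11.5, E12.5 and E13.5, 425-fold higher at E13.5 than at E11.5 (243 to 823). Its log2 ratio of 8.73 depended on the spots taken: it was 6.67 when spots of several classes were put in the class of highest rank and 6.32 with the top 5% of spots. In the E11.5 region led by cartilage genes, which held 3 of the 36 chondrogenic spots, Col11a2 stood at 108 CPM. Comp, a matrix protein of maturing cartilage, was 988-fold higher (176 to 39093) and near 1 CPM until E12.5. Snorc, a chondrocyte proteoglycan, was at least 238-fold higher (exact interval from 193) and Col10a1, the collagen of hypertrophic cartilage, at least 99.1-fold higher (exact interval from 79.6), each against 0 UMIs at E11.5. Cytl1 (182-fold), Susd5 (176-fold), Trpv4 (122-fold), Prelp (76.9-fold), Chadl (74.2-fold) and Mia (47.3-fold) were higher as well.

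Lower in the chondrogenic spots at E13.5 were Nnat (1231, 597 and 144 CPM, 8.53-fold, 6.63 to 11.2), Fabp7 (15.7-fold) and Nr2f1, a nuclear receptor of early mesenchyme and nerve (8.66-fold). Id2, an inhibitor of basic helix-loop-helix factors, was 4.89-fold lower, and Mecom (5.34-fold), Gpx3 (4.81-fold), Hsph1 (4.13-fold), Ctxn1 (3.74-fold), Limd2 (3.52-fold) and Marcksl1 (3.51-fold) were lower too. At E11.5, 9 of the 36 chondrogenic spots lay in a region led by Penk, Tbx1 and Mecom. The spots taken can therefore set part of these lower levels. In all, 593 genes were at least 2-fold higher and 377 at least 2-fold lower of 4879 with at least 50 UMIs, and for 284 and 87 the interval lay beyond 2-fold. Of the genes past 2-fold, 61.1% were higher. That share depended on the scaling: it was 50.5% with TMM factors, which shifted all log2 ratios by -0.13, and 45.0% when globin, mitochondrial and ribosomal protein genes were left out of the total (-0.19). Heart genes were lower at E13.5 in these spots (7 of 7 at least 2-fold, median log2 ratio -2.40).

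The gene lists told the same spots apart by programme. Of 18 measured cartilage matrix genes 17 were at least 2-fold higher at E13.5 (median log2 ratio 5.47, or 5.53 with the gene at 0 set to its bound), at percentile 100 of random lists of like expression. At E11.5 only 3 of the 36 chondrogenic spots lay in the region led by cartilage genes, while 52 of 70 lay in 1 such region at E13.5. The spots taken can therefore set part of this median. Of 7 hypertrophic and osteogenic genes 7 were higher (median 3.02, or 3.14 with 3 genes at their bound), Pth1r, Runx2 and Ihh among them. Fibrous matrix genes were higher in 18 of 20 cases (median 2.98), with Col1a1 at 187, 202 and 2188 CPM and Bgn at 144, 138 and 1847. Imprinted growth genes were higher in 8 of 10 cases (median 1.56), led by Meg3 (19.04-fold, 16.4 to 22.2) and Dlk1 (9.25-fold, 8.10 to 10.6). Mesenchymal transcription factors were lower in 7 of 13 cases and higher in 1 (median -1.06, or -1.19 with Msx1 at its bound), for example Twist2 (4.99-fold lower) and Prrx2 (3.16-fold lower). The spots taken can set part of this median too. At E11.5, 5 chondrogenic spots lay in a region with Msx1 and Prrx1 among its leading genes. In another with Msx1, Prrx1 and Prrx2 among them lay 3. Of 16 proliferation genes 0 passed 2-fold, yet their median of -0.51 lay at percentile 0.45.

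To follow the mesenchyme around the cartilage, sclerotomal spots were compared between the same sections. Fibrous connective tissue genes were higher at E13.5. Ogn, a small proteoglycan of connective tissue, stood at 21.8, 20.5 and 803 CPM (36.9-fold, 24.0 to 59.9), Postn, a matrix protein of fibrous tissues, at 79.8, 80.9 and 1411 (17.7-fold) and Col1a1 at 207, 234 and 3049 (14.7-fold). Aspn, a small proteoglycan of the outer disc and perichondrium, was at least 75.1-fold higher, Dpt, a dermal matrix protein, at least 31.9-fold and Col8a1 95.2-fold. The cartilage genes Comp (126-fold), Snorc (at least 37.1-fold) and Col11a2 (76.3-fold) and the muscle genes Tnnc2 (150.1-fold), Acta1 (71.5-fold), Mylpf (59.9-fold) and Sln (at least 33.4-fold) were higher in the same spots. Among the genes with the largest ratios, lower at E13.5 were Igfbpl1 at least 51.0-fold, Ina, a neurofilament-related protein, 15.6-fold, Crmp1 15.3-fold, Tagln3 6.69-fold and Dpysl4 5.45-fold. Slc4a1, the red cell anion exchanger, was 64.5-fold lower, and the transcription factor Meis2 9.62-fold.

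In sclerotomal spots 840 genes were at least 2-fold higher and 251 at least 2-fold lower of 7114. Of 20 fibrous genes 18 were higher (median log2 ratio 3.09), and of 18 cartilage matrix genes 16 (median 4.46, or 3.82 with 3 genes at 0 set to their bound). Genes of other tissues and Hox genes differed in the same spots: macrophage genes were higher in 3 of 4 cases (median 1.29, percentile 99.4), and Hox groups 9 and 10 higher in 4 of 7 and lower in 2 (median 1.15, percentile 99.8). Hedgehog response genes were higher in 5 of 11 cases and lower in 2 (median 0.82, percentile 99.7): Hhip, an antagonist that hedgehog signals induce, was 10.0-fold higher (4.39 to 28.1) and Gas1 4.47-fold higher, while Foxf1 and Foxf2 were 3.38-fold and 6.21-fold lower. Wnt genes were lower in 6 of 11 cases and higher in 3 (median -1.02), with the antagonist Wif1 13.6-fold higher and Dkk1, another, 13.9-fold lower (3.42 to 122).

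To follow the notochord as it becomes the nucleus pulposus, notochord spots were compared between E13.5 and E11.5. Cartilage matrix genes were higher at E13.5, while notochord genes went both ways. Car3 stood at 186, 309 and 6218 CPM (33.4-fold, 28.8 to 38.8), Krt8 at 111, 218 and 1076 (9.73-fold, 7.83 to 12.2) and Krt19 at 44.0, 32.4 and 545 (12.4-fold). T, which chooses the spots, was 12.4-fold higher as well (10.0 to 15.6). Of the class spots, 29 of 47 held T at E11.5 and 38 of 41 at E13.5. The share of notochord in the class and a change within it are therefore not told apart. Spp1, osteopontin, was 102-fold higher (54.7 to 216) and Ndufa4l2, a mitochondrial gene induced by hypoxia, 107-fold (48.3 to 297). Snorc (53.3-fold), Col11a2 (33.9-fold), Col16a1 (35.0-fold), Col6a3 (27.4-fold), Col6a1 (20.6-fold) and Ptgs1, a cyclooxygenase (50.2-fold), were higher, as was the muscle gene Mylpf (52.9-fold). Foxa1 was 3.18-fold lower (1.39 to 8.94), Foxa2 9.92-fold (1.68 to 402) and Ntn1 3.09-fold (1.82 to 5.63). With the class chosen by T alone the ratio of E13.5 to E11.5 was 0.877 (0.394 to 1.77) for Ntn1 and 0.343 (0.0896 to 0.941) for Foxa1, and Foxa2 held 5 UMIs at E11.5 and 0 at E13.5. Krt18 was level at 103, 113 and 103 CPM. With the class chosen by T alone its ratio was 1.59 (0.968 to 2.55), and those of Krt8 and Krt19 were 14.2 and 18.4.

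Among the genes with the largest ratios, lower in the notochord spots at E13.5 were several that are expressed in the neural tube. Hes5, a Notch target of neural progenitors, was at least 12.2-fold lower, Mir9-3hg at least 11.4-fold, Sox2, a factor of neural progenitors, 31.0-fold (5.46 to 1235) and Fgfbp3 72.7-fold (12.95 to 2883). Hist3h2ba (at least 12.4-fold), Hoxb5os (66.1-fold), Fam210b (38.1-fold), Dpysl4 (37.6-fold), Fam183b (33.3-fold) and Hoxb8 (27.7-fold) were lower too. Regions led by Msx3, Hes5 and Sox2 held 85 spots at E11.5 and 36 at E12.5, and no region at E13.5 was led by these genes. Over all spots Hes5 stood at 66.6, 38.1 and 1.11 CPM, so its lower level was not limited to notochord spots. Spots with Shh and no T, 16 at E11.5, 5 at E12.5 and 2 at E13.5, were part of the class. In all 366 genes were at least 2-fold higher and 632 at least 2-fold lower of 4763. The interval lay beyond 2-fold for 187 of the higher and 143 of the lower genes, so that there more were higher. The split depended on which spots were taken, with 707 and 631 genes when the class was 6% of spots and 422 and 413 with spots of at least 5000 UMIs.

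Of 17 cartilage matrix genes 14 were higher in notochord spots (median log2 ratio 3.56, or 3.58 with 2 genes at their bound), and of 20 fibrous genes 16 were higher and 1, Dcn, was lower (4.02-fold, although higher at E13.5 with the class at 6% of spots). Glycolysis and hypoxia genes were higher in 7 of 11 cases (median 1.12, percentile 99.9), with Ldha at 759, 1567 and 2177 CPM, Pgk1 at 435, 703 and 943 and the mitophagy gene Bnip3 at 69.3, 202 and 280.0. Heart genes were higher in the same spots (median 1.35, percentile 99.8), and epidermis genes summed to 45.9, 20.1 and 225 CPM. Hox groups 4 and 5 (median -2.62, or -2.22 with 2 genes at their bound), 6 to 8 (-2.42, or -2.11 with 1 gene at its bound) and 9 and 10 (-2.80) were lower. Notch genes were lower in 7 of 8 cases (median -2.04, or -2.32 with Hes5 and Hey1 at their bound). Mesenchymal transcription factors were lower in 6 of 10 cases (median -1.52, or -1.24 with Msx1 at its bound). The notochord sheath and nucleus pulposus list itself went both ways, with 4 of 10 genes higher and 3 lower (median 0.39, percentile 95.3).

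**Figure D3:**
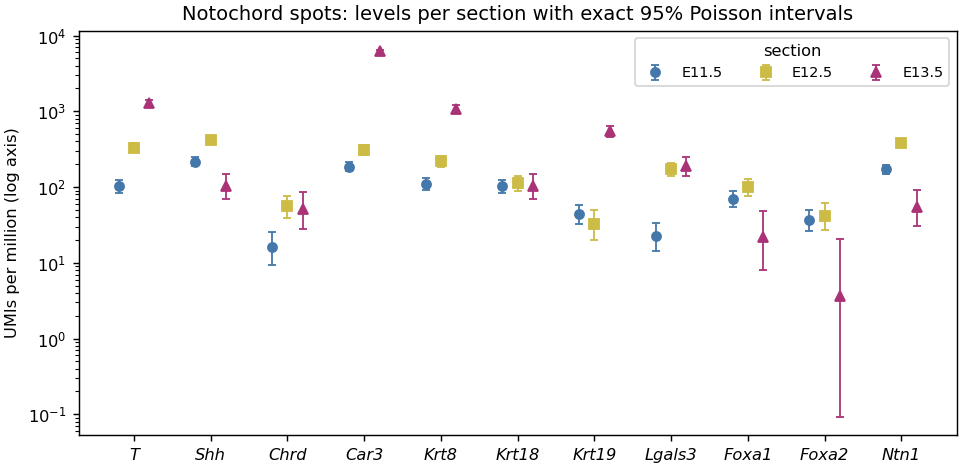
CPM (log axis) of notochord genes in the notochord spots of the E11.5, E12.5 and E13.5 sections, with 95% Poisson intervals; T, Shh and Chrd choose the spots. Car3 stands at 186 at E11.5 and 6218 at E13.5 and Krt8 at 111 and 1076, while Ntn1 ends at 55.3 and Foxa2 at 3.68.

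To see the sections as a whole, all spots with at least 1000 UMIs were summed per section. Among the genes with the largest ratios, higher at E13.5 were Myh8, a fetal muscle myosin, at 0.744, 16.8 and 372 CPM (499.9-fold, 356 to 727), Ibsp, bone sialoprotein, at 0.0225, 0.0392 and 26.4 (1171-fold, 210 to 46314) and Cma1, a mast cell protease, at 0.0225, 0.706 and 60.3 (2674-fold, 479 to 105671). Tpsb2, a second mast cell protease, was at least 172-fold higher, Cxcl9 at least 80.7-fold, Fam180a at least 82.3-fold, Col10a1 at least 100.3-fold, Atp1b4 847-fold, Aspn 367-fold and Comp 349-fold. Lower were genes of neural progenitors such as Msx3, at 21.01, 10.9 and 0 (at least 201-fold). The E13.5 section held no region led by such genes, so that section content and stage are not separated here. Atoh1 was at least 71.1-fold lower, Olig3 323-fold and Neurog2 306-fold. Lhx3 (at least 135-fold), Prdm13 (at least 51.9-fold), Sp8 (at least 37.2-fold), Otx2 (at least 34.8-fold), Msx2 (426-fold) and Robo3, a receptor of commissural axons (356-fold), were lower as well.

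Over all spots 2219 genes were at least 2-fold higher at E13.5 and 1212 at least 2-fold lower of 15232, 64.7% of them higher, or 57.1% with TMM factors, which shifted all log2 ratios by -0.14. Across all spots, fibrous genes were higher in 19 of 20 cases (median 3.46), cartilage matrix genes in 15 of 19 with 1 lower (median 3.19) and hypertrophic and osteogenic genes in 10 of 13 (median 1.72). FGF genes were higher in 5 of 11 cases and lower in 1 (median 0.93, percentile 99.5) and TGF-beta and BMP genes in 7 of 20 (median 0.58, percentile 99.7). Of the medians of 101 lists in the 4 sets of spots, 68 lay outside the central 95% of random lists.

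**Figure D4:**
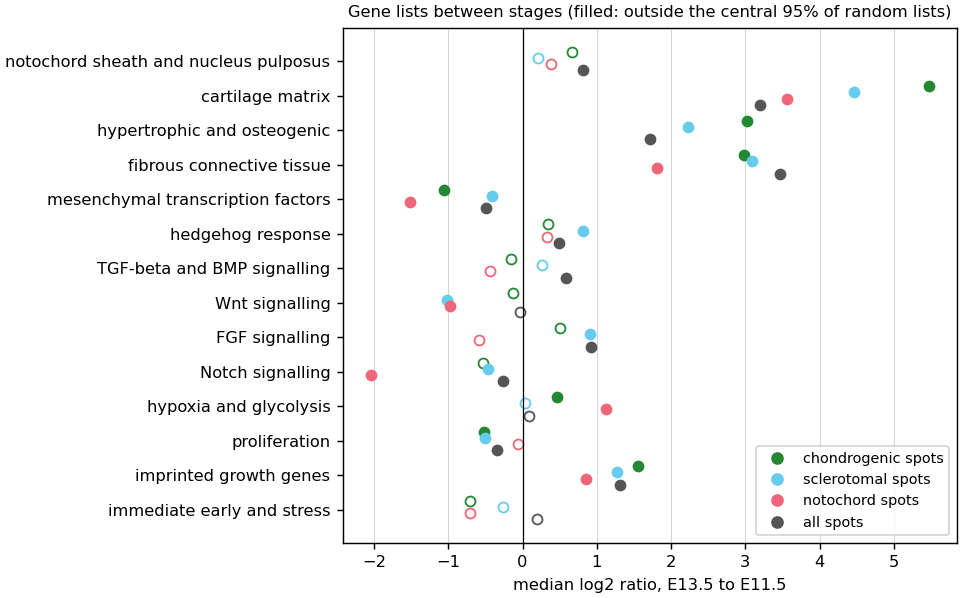
Median log2 ratio of E13.5 to E11.5 (horizontal axis) of 14 gene lists in chondrogenic, sclerotomal, notochord and all spots, with filled points outside the central 95% of 10000 random lists. Cartilage matrix medians reach 5.47, 4.46, 3.56 and 3.19, and the Notch median in notochord spots lies at -2.04.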

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

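The tests of the floor plate genes and of the diverging notochord genes, the muscle test in CPM and the 2-fold bound for Postn were chosen after seeing results, and both tests of the notochord genes replaced earlier versions, which rested on T and Shh, genes that choose the spots, had a bound no gene met, or counted genes that define the pattern. A test of scaling by T and Shh was dropped for the same reason. Postn, a matrix protein of tendon and fibrous tissue, went in opposite directions between sections in the tendon comparison. Its ratio of tendon to chondrogenic spots was 0.265 (0.212 to 0.331) at E11.5, 7.85 (5.46 to 11.7) at E12.5 and 2.96 (2.64 to 3.33) at E13.5, and the difference was not tested. With intervals that only exclude 1, 18 of 201 list genes went in opposite directions between sections in the tendon comparison, 13 in the notochord and 11 in the sclerotomal one.

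Genes of the floor plate, the ventral midline of the neural tube that expresses Shh without T, were among those higher in notochord spots. Of the 24 genes called, 17 were at least 2-fold higher in class spots with Shh and no T than in those with T, at both E11.5 and E12.5, and 1, Car3, was at least 2-fold lower in both. At E11.5 and E12.5, spots with Shh and no T are therefore a likely source of part of Slit1, Fam183b and their like. Whether these spots are floor plate was not tested. Spots with T still held Slit1 at 49.1, 20.9 and 30.9 CPM in the 3 sections, against 3.25, 0 and 2.26 in chondrogenic spots. Fam183b stood at 57.0, 0 and 3.87 CPM in spots with T, against 2.17, 0 and 0. At E13.5 the 2 spots with Shh and no T stood at 0 CPM for both genes. The 2 classes were of like depth, with the ratio of median UMIs per spot farthest from 1 at 0.820, so a depth difference between them is an unlikely source. An effect of depth on which spots were chosen was not tested.

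Krt8, Krt19 and Car3 were higher and Foxa1, Foxa2 and Ntn1 lower at E13.5 than at E11.5 in notochord spots. With the class chosen by T alone, 2 of the 3 lower genes, Foxa2 and Ntn1, had intervals that reached 1, and that of Foxa1 ended at 0.941. Fewer spots with Shh and no T at E13.5 therefore stay open as the source, and Foxa2 held only 5 UMIs at E11.5. A larger share of notochord cells per spot stays open too: of the 3 list members outside this pattern with at least 20 UMIs, 2 (Krt18 and Cd24a) had upper bounds below the lower bounds of Krt8, Krt19 and Car3, and Lgals3 did not.

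Muscle genes such as Mylpf were higher at E13.5 in notochord spots. The tests used 20 genes chosen as high in myogenic and far lower in neural spots, and Mylpf was not among them. In UMIs per spot the notochord class held 0.352 of the neural class (median of 20 muscle genes), a value outside both ranges predicted beforehand, so that spread of muscle RNA over the section stays open. In CPM the ratio was 1.17, within the range that a like share of muscle RNA in these 2 classes would give. The neural level was part of the choice of the genes, so this ratio cannot decide on a like share. Other classes differed: Acta1 stood at 451 CPM in chondrogenic, 335 in notochord and 243 in neural spots. Muscle cells in a few spots were excluded for these 20 genes, as 22.3% of their 573 UMIs lay in the 5 spots with the most.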

How the results depend on the processing

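The notochord class from T alone, the removal of spots with heart genes and the minimum of 5000 UMIs were chosen after seeing the data. Of 195 results of the comparisons 121 stayed the same, 724 of 5099 stage values moved and 4 reversed, and 192 of 661 region values were weaker. Pairs give genes higher and lower, for notochord (N), sclerotomal (S) and tendon (Tn) against chondrogenic spots, and the cause was not tested. DESeq2 gave N 76 and 7, S 2 and 19, Tn 26 and 71. Without a filter these were N 62 and 6, S 2 and 19, Tn 22 higher. Classes of 1.5% and 5% gave N 10 and 0, Tn 36 and 90, with 363 and 244 genes between stages in chondrogenic and 188 and 300 in notochord spots. There Gli1 in chondrogenic spots reversed to -0.24 and Frzb in sclerotomal spots to 0.70. Classes of 6% and 20% gave N 12 and 0, S 1 higher, Tn 1 and 17, with 654 lower in chondrogenic and 707 higher in notochord spots. There Dcn reversed to 0.78 and Sfrp2 to 0.48 in notochord spots. Z-scores gave N 15 higher, S 3 lower and 396 lower between stages in notochord spots. Spots put in the class of highest rank gave N 50 higher and S 0 lower. Spots of any depth gave S 1 higher. The gene T alone gave N 1 and 0, S 8 lower. At least 5000 UMIs gave N 0 lower, S 1 lower and 413 lower between stages in notochord spots. Without heart spots Tn was 17 higher. Without the section block, counts were N 0 and 0, S 0 lower, Tn 0 and 0. Only 2 classes in the model gave N 68 and 30, S 52 and 78, Tn 26 higher. An estimated correlation left 3 lists of 32. At least 10 UMIs with a pseudocount of 0.5 UMI gave 1730 and 989 genes in chondrogenic, 1919 and 786 in sclerotomal and 1361 and 1688 in notochord spots, and at least 200 UMIs gave 130 and 90, 227 and 65, 75 and 96. With each section left out in turn N ranged over 0 to 77 and 0 to 13, S over 0 to 0 and 0 to 6, Tn over 0 to 16 and 3 to 52, and lists over 26 to 32.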

Other observations

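Globins differed between the sections: embryonic genes gave 89.7% of beta-globin UMIs at E11.5, 83.6% at E12.5 and 5.48% at E13.5. Small regions at E13.5 showed cell types beside the skeleton. Mast cell genes led 46 spots, with Cma1 at 1028 CPM against 25.6 elsewhere and Cpa3 at 676 against 14.6. Sympathetic genes led 41 spots, with Dbh, which makes noradrenaline, at 327 against 4.70 and Phox2a at 252 against 3.25. Sftpc, a surfactant gene, stood at 992 against 29.7 in a region of 97 spots led by lung genes. The 12 spots led by bone genes held Ibsp at 3438 against 5.25 and Col10a1 at 965 against 0.840, and of the class and other tissue lists liver was the one most raised there (mean log2 ratio 3.01).

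The sections also differed in the organs they held. Liver genes summed to 765, 12.3 and 89.9 CPM at E11.5, E12.5 and E13.5, heart genes to 1622, 77.5 and 1453, and macrophage genes to 86.5, 103 and 304. Regions led by Msx3, Hes5 and Sox2, genes of neural progenitors, held 85 spots at E11.5 and 36 at E12.5, and no region at E13.5 was led by them. Hox groups 9 and 10 summed to 148, 466 and 185 CPM over all spots, but to 48.8, 421 and 214 in chondrogenic and 197, 412 and 107 in notochord spots. From E11.5 to E13.5 the other groups went the same way in these classes. Groups 4 and 5 went from 67.2 to 122 CPM in chondrogenic and from 277 to 70.0 in notochord spots, and groups 6 to 8 from 71.6 to 147 and from 345 to 58.9. Whether axial level or other content of the spots differs between the stages was not tested. Xist, expressed in females, held 4303 UMIs at E11.5 and 0 at E12.5 and E13.5, while Y-linked genes held 0 at E11.5 and 102 and 107 CPM later, so that sex goes with stage.

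The splits were planned before results were seen. Of 10 ways to split the 6 sums of a comparison into 3 against 3, 1 gave as many genes as the real classes for notochord (26 genes), sclerotomal (5) and tendon spots (47), namely the real one, and the highest other split gave 0, 0 and 1. The classes are paired by section, and 4 of the 10 splits part all pairs, while the other 6 put both classes of a section on the same side. Among the 4, the splits other than the real one gave 0 genes in each comparison. So few splits cannot give a share under 0.05.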
